A study of Bradyrhizobium diazoefficiens USDA 110 with 6 samples.

How the data were processed

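RNA of Bradyrhizobium diazoefficiens, a soil bacterium that nodulates soybean, was compared between chemoautotrophic cultures supplemented with arabinose and chemoautotrophic cultures without it. Per the labels, 3 independent biological materials of each culture were prepared, total RNA was extracted with hot phenol, and 10 ug was copied into cDNA from random hexamers before labelling with Cy3 or Cy5. Each of the 3 pairs of RNA was hybridised on 2 arrays with the dyes exchanged, which gave 6 arrays, 3 with arabinose in Cy5 and 3 with arabinose in Cy3. The 2 arrays of a replicate number hold the same 2 extracts and were counted as 1 replicate, so n = 3.

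The deposited values are normalized log2 ratios, which the authors describe per the labels as arabinose-supplemented over plain chemoautotrophy on every array. The scanner, the background correction, the normalization method and any averaging of spots are not given in the sources used here. The table held 8480 rows. The column medians lay between -0.024 and 0.0019, so the columns were already centred near 0, and the SD over rows ran from 0.227 to 0.392. No spot intensities were used, so signal over background is unknown. The number of arrays limits the precision.

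The stated direction was in doubt. The 2 columns of a replicate correlated negatively across rows, with a Pearson r over genes tested of -0.579, -0.488 and -0.398 in replicates 1, 2 and 3, where 2 columns of the same ratio of the same extracts would correlate positively unless dye bias exceeded the ratio. As fixed before the data were examined for such a case, the direction was set from the dyes. Columns with arabinose in Cy5 were kept as deposited, since the stated ratio is then Cy5 over Cy3, and columns with arabinose in Cy3 were turned in sign. The direction of every signed value therefore rests on this choice and is not settled. If instead the arabinose-in-Cy5 columns had the wrong sign, each positive value would be negative and each test would give the same p. A second doubt concerns replicate 1, whose arabinose-in-Cy3 array correlated at r = -0.330 with that of replicate 2, although both compare the same conditions in the same dyes. The direction of replicate 1 relative to the others is thus not settled either, and gene counts, called lists and named genes are also given with replicate 1 turned. Genes are not independent replicates in any of these correlations.

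After turning, the same-numbered arrays correlated at 0.579, 0.488 and 0.398, and their values were averaged within each replicate. Because same-numbered arrays share their extracts, the replicate numbers pair them, and a fit of all 6 arrays with the replicate as a block and a dye term was run as the alternative. That blocked fit called 0 genes. No 2 columns were identical. The half-sum of the deposited columns, in which the RNA ratio cancels once the direction is as set here, measured the dye effect.

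A gene was tested if it had a value on all 6 arrays. That left 8282 rows and, after averaging rows of one gene, which concerned 183 genes, 8082 genes. Gene symbols came from the platform annotation supplied with the array. It did not list 18 rows, which were kept under their own identifiers, and 6655 tested genes had no symbol other than their locus name. Product names and genome positions were not used here, so loci are given by the identifier, whose number follows gene order. The mean log2 ratio of the 3 replicates was tested against 0, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over 8082 genes and a threshold of 0.05. Every adjusted p of a gene given here is from limma. Fold bounds of 1.5 and 2 were counted as well. Of 31 gene lists fixed before the data were examined, 25 had at least 4 measured members and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The remaining 6 lists had too few members recognisable by symbol. List p-values were adjusted over 25 lists. Where no other test is named, a called list is one past 0.05 by camera at the preset correlation. That setting takes members as nearly independent, so its p-value does not measure the spread of the list mean between replicates. Where members vary together, as neighbouring loci did here, it is too small, and such a call alone is no evidence of an arabinose response. Means of lists are given with the SD of the 3 replicate means. Runs of at least 4 neighbouring loci were set against 1000 permutations over loci.

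Named genes followed a rule fixed before the data were examined: the genes with the largest changes among those past the threshold, of which there were none, and the 3 members with the smallest adjusted p, with ties put in order of unadjusted p, of each called list and of the Calvin cycle, hydrogenase, nitrogen fixation, cbb3 oxidase, central carbon, TCA cycle and pentose lists. The rule also named a sugar ABC transporter list, which was among those with too few members. It gave 30 genes, and any gene outside the rule is said to have been chosen after its values were seen.

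The steps were tested on simulated data of 8082 genes with the spread of these replicates, with 100 changed genes of each size in each of 20 simulations. The test recovered 68.1% of 2-fold changes and 89.7% of 4-fold changes, with a mean of 5.9 false calls per simulation. Changed genes were drawn at random, so these shares hold for genes of typical spread (median SD 0.164) and for the number of changes set. With the direction set from the dyes, the 4 measured genes with a mean over 2-fold had SDs from 0.78 to 1.64. Recovery of genes with such a spread was not measured. A list shifted by 0.3 was recovered in 20 of 20 simulations, with a mean of 0.1 false lists. Genes were drawn independently of each other, so these figures do not measure false calls among lists whose members vary together. Alternatives covered centring, scaling, missing values, the treatment of dye swaps, single dye orientations, the variance prior, array weights, a fold bound, rows tested singly, removal of the genes of smallest spread, list membership and each replicate left out. Added after the data were seen were the reading of all columns as the labels state, replicate 1 turned, a test without moderation, scaling for the lists, runs of same-sign genes, the hydrogenase list limited to 1 cluster, and the estimated correlation and fry with replicate 1 turned or a replicate left out. With a replicate left out, too few replicate means remain to estimate a correlation between genes. The estimated-correlation values of those settings can therefore neither back nor undo a call. Figures were drawn with matplotlib 3.10.9.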

Results

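The 6 arrays measured transcript ratios in Bradyrhizobium diazoefficiens growing chemoautotrophically, that is with carbon dioxide as carbon source and an inorganic electron donor such as hydrogen. The comparison asked which genes respond when arabinose, a pentose sugar, is supplied to such cultures. Each of 3 replicate pairs of cultures was measured on 2 arrays with exchanged dyes, and 8345 to 8451 of 8480 rows had a value per array. All values are log2 ratios of arabinose-supplemented over plain cultures with their SD over n = 3 replicates. Their direction is assumed, not settled. The 2 columns of a replicate run opposite ways, and the arabinose-in-Cy5 columns were kept as deposited. No test here could tell which orientation, if any, carries the wrong sign.

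With the direction set from the dyes, no single gene passed the test over all genes, including those of carbon dioxide fixation and hydrogen oxidation. The large Rubisco subunit gene cbbL (blr2585) had a ratio of 0.94 ± 0.43 and the hydrogenase large subunit gene hupL (bll6941) one of 0.73 ± 0.23, both with an adjusted p of 0.824, and with replicate 1 turned they stood at 0.60 and 0.41. Of 8082 genes, 0 were higher and 0 lower at an adjusted p of 0.05 in limma, so 0 also passed with a bound of 1.5-fold or 2-fold. At an unadjusted p under 0.05 there were 414 genes, 217 higher and 197 lower, against 404.1 from chance alone. An ordinary one-sample test without moderation also gave 0, and the fit with the replicate as a block gave 0. The count of 0 depends on the direction chosen. With all 6 columns read as the labels state, limma gave 820 genes higher and 996 lower, described below as the dye effect. In that reading cbbL stood at 0.26 (limma adjusted p = 0.00326) and hupL at 0.24 (limma adjusted p = 0.0112).

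The size of any change was bounded by the spread of the replicates. The median SD between replicates was 0.164, the median 95% interval reached 0.257 to either side of the mean, and for 97.0% of genes the interval lay within 2-fold in both directions. There were 4 genes with a mean ratio over 2-fold higher and 0 over 2-fold lower. These 4, chosen after their values were seen, were hupC (bll6940) at 1.10 ± 0.78, hupF (bsl6938) at 1.12 ± 0.82, and the neighbours bll3147 at 1.10 ± 1.39 and bll3148 at 1.11 ± 1.64. Without replicate 2, hupC and hupF stood at 0.66 and 0.64, and bll3147 and bll3148 were at -0.36 and -0.70 in replicate 1. The sign was the same in all 3 replicates for 29.0% of genes, where chance gives 25%. Across genes, replicates 2 and 3 correlated at r = 0.421, but replicate 1 correlated at -0.379 with replicate 2 and at -0.219 with replicate 3. With replicate 1 turned, 0 genes passed as well, the smallest adjusted p was 0.106, and 1194 genes had an unadjusted p under 0.05, 748 higher and 446 lower. The interval then lay within 2-fold for 97.5% of genes and the sign was the same in all 3 replicates for 38.7%. The mean ratio was then over 2-fold higher for 33 genes, with the chaperone genes clpB (blr1404) at 1.63 ± 0.97 and groEL (blr5626) at 1.34 ± 0.77 among them, bll3147 at 1.34 and bll3148 at 1.58, while hupC and hupF stood at 0.54 and 0.66. It was over 2-fold lower for 1 gene, bll0333, at -1.05 ± 1.05. The genes named in these 2 sentences were chosen after their values were seen.

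The Calvin cycle list holds genes of carbon dioxide fixation, but also the regulator gene cbbR (bll2580) and blr2588, which has no symbol. It had a mean of 0.48 ± 0.20 over its 10 measured members, 9 of them above 0. Of the 9, cbbP (blr2582) and cbbT (blr2583), chosen after their values were seen, were above 0 through replicate 3, and their means without it were -0.12 and -0.05. A further member so chosen, cbbY (bll6838), at 0.018, was -0.081 without replicate 3 and -0.0047 without replicate 1. Members above 0 were 8, 10 and 7 without replicates 1, 2 and 3. Besides cbbL, the smallest unadjusted p-values, which broke ties of the adjusted p, belonged to cbbX (blr2587), a Rubisco activase gene, at 0.84 ± 0.45, and to the aldolase gene cbbA (blr2584) at 0.78 ± 0.51. Adjusted over the list alone, 5 of the 10 members passed and 0 passed over all genes. The 5 were cbbL, cbbX, cbbA, cbbS (blr2586) and blr2588. The list was higher by camera at the preset correlation, which takes members as nearly independent (adjusted p = 6.64e-06). It had adjusted p = 0.454 with an estimated correlation and 0.259 by fry. None of the 5 passed without replicate 2, without replicate 3, on the arabinose-in-Cy3 arrays alone, against a 1.2-fold bound, without moderation or with replicate 1 turned, while cbbL, cbbX and cbbA passed without replicate 1. The ratios with a replicate left out ranged from 0.72 to 1.15 for cbbL and from 0.61 to 1.05 for cbbX, and those with the bound or without moderation were the same by construction. The list mean with replicate 1 turned was 0.31 (camera adjusted p = 0.0990), and cbbL stood at 0.60, cbbX at 0.31 and cbbA at 0.61.

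The hydrogenase list, taken by symbol and locus number, holds structural and maturation genes of the uptake hydrogenase. It also holds other genes with hup symbols, such as hupA (bll6175), hupT, hupU and hupV. The list had a mean of 0.23 ± 0.07 over 39 members, 28 of them above 0. The members with the smallest unadjusted p, which broke ties of the adjusted p, were hupI (bsl6935) at 0.80 ± 0.22, hupL at 0.73 ± 0.23 and hupG (bll6937) at 0.43 ± 0.07. Adjusted over the list alone, 8 of the 39 passed, and 0 passed over all genes. The cluster that runs from blr6922 to bll6949 held 25 of the members and had a mean of 0.37 ± 0.08, with 12 genes positive on all 6 turned arrays. The other cluster of hup and hyp genes, blr1720 to blr1737, had a mean of 0.01 ± 0.07 over 11 members, with 0 positive on all 6. Turning replicate 1 gave cluster means of 0.09 ± 0.45 and -0.05 ± 0.04. The difference between the clusters was not tested.

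The hydrogenase list was higher by camera (adjusted p = 5.49e-07), with adjusted p = 0.454 with an estimated correlation and 0.259 by fry. The 8 members became 0 without replicate 2, without replicate 3, against a 1.2-fold bound, without moderation and with replicate 1 turned, 2 on the arabinose-in-Cy3 arrays alone, 15 on the arabinose-in-Cy5 arrays alone or with 6 separate arrays, 14 without the tenth of genes with the smallest SD, and 12 without replicate 1, while hupL ranged from 0.63 to 0.86 with a replicate left out. With replicate 1 turned the list mean was 0.03 (camera adjusted p = 0.766, with the test pointing down while the mean was above 0), and hupI, hupL and hupG stood at 0.32, 0.41 and 0.12.

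**Figure D1:**
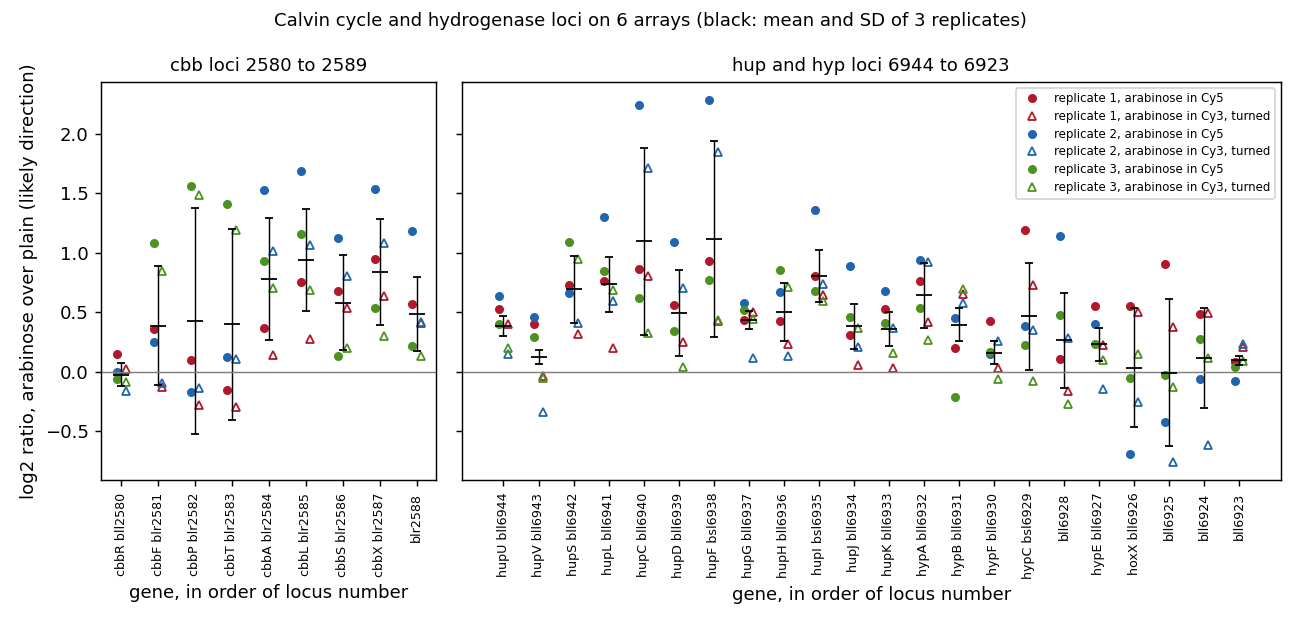
Log2 ratios (vertical axis) of the cbb genes (left) and the hup and hyp genes (right), in order of locus number on the horizontal axis. Circles are arrays with arabinose in Cy5, triangles are turned arrays with arabinose in Cy3, colours mark the 3 replicates, and black marks with bars give the mean and SD of 3 replicates. The means of cbbL (0.94) and hupL (0.73) are above 0 with all 6 arrays positive, while cbbP (0.43) has a bar that crosses 0.

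Some neighbouring loci of these clusters shared their sign on all 6 arrays. No run of called genes existed, as 0 genes were called. Among genes with one sign on all 6 turned arrays, a definition chosen after the data were seen, 278 were positive and 252 negative, and 3 runs of 4 or more neighbours occurred. The longest held 11 genes from hypA (bll6932) to hupS (bll6942) with a mean of 0.66 ± 0.23. A run of 6 from cbbA (blr2584) to blr2589 had a mean of 0.66 ± 0.31, and a run of 4 ribosomal protein genes from rplW (bll5398) to rpsJ (bll5401) had one of 0.65 ± 0.61, which was 0.31 without replicate 2. Of 1000 permutations of the signs over loci, 20 had any run of that length, 0 had 3, and the longest was 5. The permutation treats loci as independent, whereas neighbouring loci on one strand correlated at 0.363, 0.360 and 0.405 within replicates 1, 2 and 3. It therefore cannot tell an arabinose response from variation that neighbours share for other reasons. With replicate 1 turned the longest run was 6 genes, from blr1480 to blr1485, and there were 13 runs of 4 or more.

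Ribosomal protein genes had a mean of 0.32 ± 0.10 over 52 members, 49 of them above 0 (camera adjusted p = 1.27e-19, and adjusted p = 0.396 with an estimated correlation). The values were 0.40 ± 0.11 for rplU (blr0420), 0.38 ± 0.15 for rplT (bll0707) and 0.35 ± 0.14 for rplA (bll5414), none past the threshold over all genes or adjusted over the list alone. Its mean with replicate 1 turned was 0.16 (camera adjusted p = 0.000857, and adjusted p = 0.770 with an estimated correlation), and these 3 genes stood at 0.14, 0.24 and 0.22. It was the only one of the 8 called lists that camera also called then, with adjusted p = 0.645 by fry. The dye effect of this list, which averaging removes, was 0.155 (camera adjusted p = 6.38e-10).

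ATP synthase genes had a mean of 0.30 ± 0.13 with 8 of 8 members above 0 (camera adjusted p = 7.65e-07, and adjusted p = 0.454 with an estimated correlation). The 2 genes annotated atpA, bll1188 and bll0442, had ratios of 0.35 ± 0.10 and 0.36 ± 0.21, and atpB (bll1185) one of 0.42 ± 0.29. Turning replicate 1 gave a list mean of 0.17 (camera adjusted p = 0.0643), and these genes stood at 0.19, 0.07 and 0.35.

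Genes of central metabolism had small positive means. The list of glycolysis, gluconeogenesis, Entner-Doudoroff and pentose phosphate genes had a mean of 0.13 ± 0.04, with 13 of 15 members above 0 (camera adjusted p = 0.00197, and adjusted p = 0.454 with an estimated correlation). Within it, pckA (bll8141), which encodes a gluconeogenic carboxykinase, had 0.38 ± 0.20, the pyruvate kinase gene pykA (blr7138) -0.27 ± 0.17 and rpiA (blr3755), a pentose phosphate isomerase gene, 0.19 ± 0.05. The TCA cycle list had a mean of 0.14 ± 0.09, with 10 of 13 above 0 (camera adjusted p = 0.00587, and adjusted p = 0.535 with an estimated correlation), and sucA (bll0452), sdhD (blr0513) and sucD (bll0453) had 0.19 ± 0.02, 0.24 ± 0.16 and 0.66 ± 0.69. Neither list was called with replicate 1 turned, both at a camera adjusted p of 0.287 and with means of 0.07 and 0.09. The TCA cycle list was also lost without replicate 3 (mean 0.08, camera adjusted p = 0.114), when sucD stood at 0.29. The 6 genes named here, with replicate 1 turned, ranged from -0.21 for pykA and -0.03 for pckA to 0.65 for sucD.

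Nitrogen fixation genes had a mean of 0.14 ± 0.10, with 17 of 22 members above 0 (camera adjusted p = 0.00222, and adjusted p = 0.531 with an estimated correlation). The nitrogenase subunit gene nifK (blr1744) had 0.36 ± 0.24, and nifN (blr1746) and nifQ (blr1770), which serve cofactor assembly, 0.36 ± 0.08 and 0.36 ± 0.13. Denitrification genes had a mean of 0.20 ± 0.19, with 13 of 18 above 0 (camera adjusted p = 0.00443, and adjusted p = 0.535 with an estimated correlation), including the nitrous oxide reductase gene nosZ (blr0315) at 0.66 ± 0.44, nosY (blr0318) at 0.35 ± 0.09 and nosX (blr0320) at 0.36 ± 0.22. Nitrogen fixation was not called without replicate 3 (mean 0.09, camera adjusted p = 0.0618) and denitrification not without replicate 2 (mean 0.10, camera adjusted p = 0.0850), when nosZ stood at 0.41. With replicate 1 turned their means were 0.12 and 0.18 (camera adjusted p = 0.111 and 0.0656), nifK, nifN and nifQ stood at 0.10, 0.15 and 0.22, and nosZ, nosY and nosX at 0.48, 0.17 and 0.10.

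Of 25 lists, 8 were called higher, 0 lower and 17 were not called, with 0 called at an estimated correlation (smallest adjusted p = 0.396) and 0 by fry for one direction (0.182) or for change either way (0.0592). Without replicate 1 the count was 13, 11 higher and 2 lower, and with replicate 1 turned it was 6, 4 higher and 2 lower. With an estimated correlation 0 were called in either setting (smallest adjusted p = 0.688 and 0.699), and by fry 0 and 1. Without replicate 1 too few replicate means remain to estimate that correlation, so the 0 there is no check on the calls. The 2 lower lists were in both cases flagella and chemotaxis (-0.14 without replicate 1 and -0.13 with it turned) and nodulation and type III secretion (-0.08 and -0.09). Pentose and sugar acid catabolism had a mean of -0.05 ± 0.11 over 4 members, uxuA, uxuB, xylA and xylB (camera adjusted p = 0.591). No list of arabinose catabolism or sugar transport genes was tested, so the response of such genes as a group is unknown. Within the pentose list, uxuB (blr6836) was at -0.14 ± 0.08, uxuA (bll6830) at -0.03 ± 0.22 and the xylulokinase gene xylB (blr1119) at -0.04 ± 0.39. With a replicate left out the list mean ranged from -0.12 to -0.0099, uxuA from -0.15 to 0.07 and xylB from -0.23 to 0.16. Turning replicate 1 gave a mean of 0.04, and the 3 genes stood at -0.07, -0.17 and 0.25.

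The list of the cbb3 oxidase, a high-affinity terminal oxidase, and its FixLJ and FixK regulators had a mean of 0.08 ± 0.36 over 19 members (camera adjusted p = 0.872). In it, 2 of the 5 genes annotated fixK, bll2109 and bll3466, had -0.35 ± 0.16 and -0.19 ± 0.05, and fixI (blr2769) had -0.16 ± 0.10. With replicate 1 turned these genes stood at -0.0047, -0.10 and -0.12. Another fixK gene, bll2757, chosen after its values were seen, changed sign between replicates. It had -1.60, 0.70 and 0.27 in replicates 1, 2 and 3, with a mean of -0.21 ± 1.22. The list mean was -0.34 in replicate 1 and 0.31 and 0.26 in replicates 2 and 3. The list was called higher without replicate 1 (0.29, camera adjusted p = 0.00205) and with replicate 1 turned (0.31, camera adjusted p = 0.000103). With an estimated correlation these were adjusted p = 0.688 and 0.699, and by fry 0.264 and 0.0411, the latter the 1 list that fry called with replicate 1 turned.

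**Figure D2:**
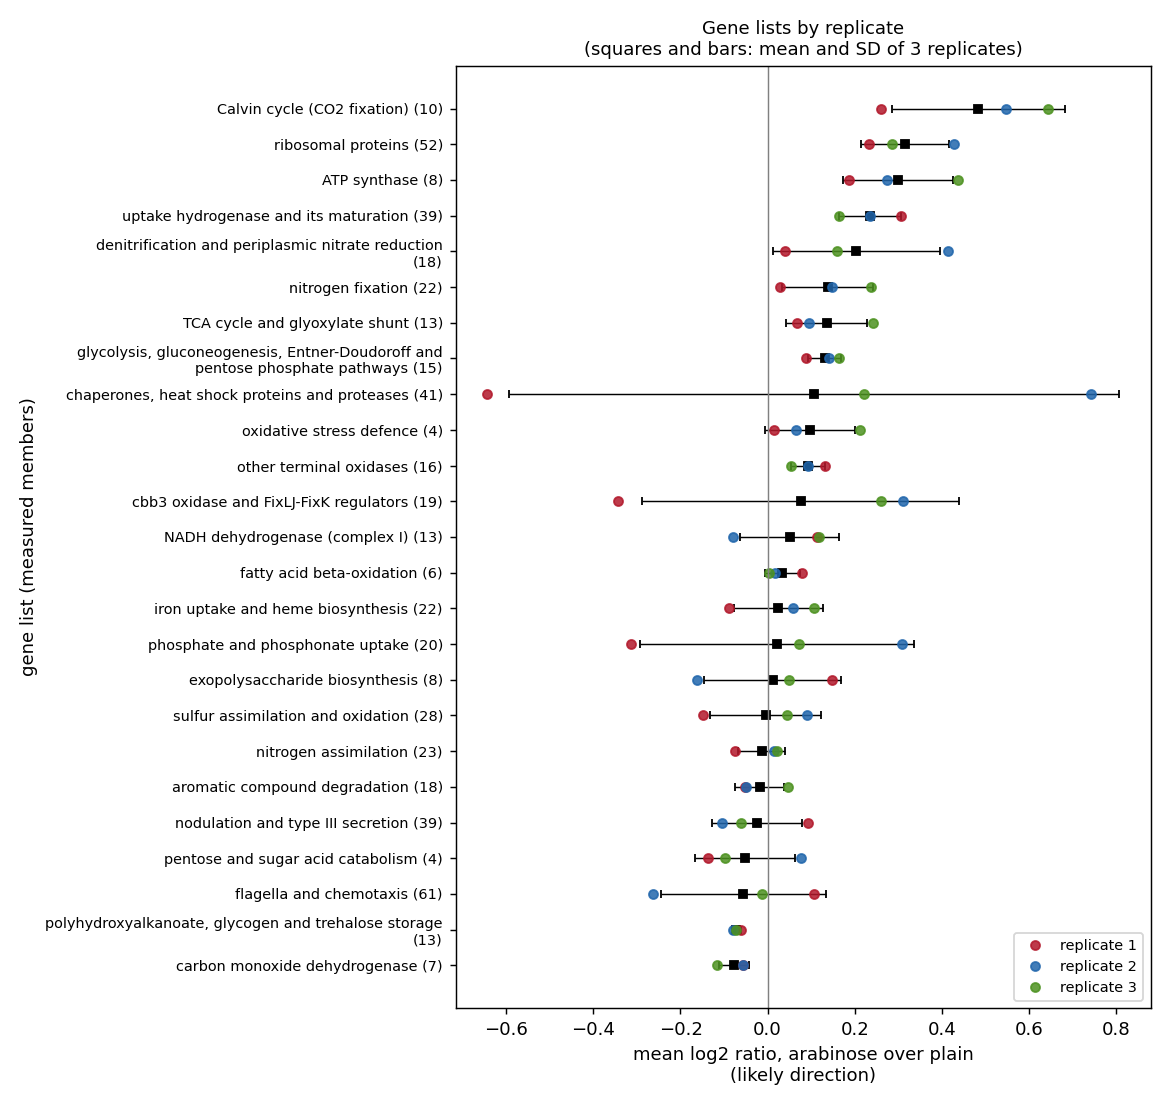
Mean log2 ratio (horizontal axis) of the members of each of the 25 tested gene lists (vertical axis, with the number of measured members). Coloured points are the 3 replicates, and squares with bars are their mean and SD. With replicate 1 as set from the dyes, the Calvin cycle list is highest at 0.48 and the chaperone list has the widest bar, with points at -0.64 in replicate 1 and 0.74 in replicate 2. With replicate 1 turned the chaperone list is highest (0.54 ± 0.28) and the Calvin cycle list has the widest spread (0.31 ± 0.50).

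The dye effect was more reproducible than the ratio between cultures. It differed from 0 at an adjusted p of 0.05 in limma for 1816 genes, 820 positive and 996 negative, or 22.5% of those tested, and for 1179 without replicate 1. It was small, with 1 and 15 of these also past a bound of 1.5-fold and 0 past 2-fold. Across genes it correlated between replicates at r = 0.606, 0.603 and 0.589. These counts would be the arabinose response if all 6 columns ran as the labels state, in which case cbbL would stand at 0.26 (adjusted p = 0.00326) and hupL at 0.24 (adjusted p = 0.0112).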

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

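The tests of explanations given here were all chosen after the values they measure had been seen.

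In 9 gene lists the mean of the deposited values was on one side of 0 on all 3 arabinose-in-Cy5 arrays and on the other side on all 3 arabinose-in-Cy3 arrays. The difference between the orientations was not itself tested. The list mean after turning was 0.48 for the Calvin cycle, 0.32 for ribosomal proteins, 0.30 for ATP synthase, 0.23 for hydrogenase, 0.20 for denitrification, 0.14 for the TCA cycle, 0.13 for central carbon metabolism, 0.093 for other terminal oxidases and -0.071 for storage compounds. The deposited Calvin cycle mean, for example, was 0.61 with arabinose in Cy5 and -0.36 with arabinose in Cy3.

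A candidate explanation for dye-swapped columns that run opposite ways is that the signs of one orientation were not turned before deposit. The half-difference of the columns would then hold the RNA ratio, and neighbouring loci on one strand, many of them in operons, should share it. Over 5287 neighbour pairs the half-difference correlated at 0.363, 0.360 and 0.405 and the half-sum at 0.142, 0.133 and 0.0594 in replicates 1, 2 and 3, a smallest gap of 0.221 with a bootstrap SE of 0.0208 in that replicate. This SE treats pairs as independent, although successive pairs can share a gene, and it measures no spread between replicates. Another candidate is gene-specific dye bias on columns that all run the same way, which belongs to the probe and should recur. With the dyes as labelled, the half-differences correlated at -0.379 between replicates 1 and 2 (bootstrap SE over genes 0.0163). Between replicates 2 and 3 they correlated at 0.421. A shared RNA ratio should recur as well, so the -0.379 goes against either reading of the half-difference. The half-sums, the ratio by the labels' reading, correlated at 0.606, 0.603 and 0.589. Recurrence therefore does not decide between the readings. With the dyes of replicate 1 exchanged, the half-differences would correlate at 0.379, 0.219 and 0.421. These are above 0 but not all at the 0.3 set for a dye bias, so a dye bias with exchanged dyes stays open. Which orientation, if any, carries the wrong sign stays open too.

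Replicate 1 ran against replicates 2 and 3. The tables argue against the listed chaperone genes alone, as the correlation of replicates 1 and 2 was still -0.357 without that list. All members of the list carry a symbol, while 6655 tested genes had none other than their locus name. A heat shock difference that reaches genes outside the list was therefore not excluded. An exchange of the RNA sources of replicate 1 cannot be told apart from a difference between cultures: of 21 lists with one sign in replicates 2 and 3, 8 (38.1%) had the other sign in replicate 1 and 13 had the same one. Turning replicate 1 brings the chaperone and cbb3 lists together and parts the hydrogenase list, so the lists pull both ways. A biological difference between the cultures of replicate 1 and the others, such as growth stage or oxygen supply, was not tested.

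With the direction set from the dyes, the Calvin cycle and hydrogenase lists had a mean above 0 in each replicate, the smallest being 0.26 for the Calvin cycle in replicate 1 and 0.16 for hydrogenase in replicate 3. No explanation of this was tested; an additive dye effect cancels in these means by design.

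Turning the signs of whole replicates gives 4 arrangements of the 3 replicates, too few for a share under 0.05. The arrangement set from the dyes gave 0 genes and the others at most 0, so all 4 had as many. It gave 8 lists, the highest of the others 6, and a longest run of 11 same-sign neighbours, the highest of the others 6. In both cases 1 of 4 arrangements, that set from the dyes, reached the value. On other measures it did not rank first. With replicate 1 turned there were 13 runs of 4 or more against 3, and the smallest adjusted p in limma was 0.106 against 0.824.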

How the results depend on the processing

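Replicate 1 turned, the reading of all columns as the labels state, the test without moderation, scaling for the lists and runs by sign were chosen after the data were seen; the cause of a difference was not tested unless stated. The count of 0 genes was the same under each alternative except the labels' reading (820 higher, 996 lower, the dye effect by construction). The smallest adjusted p in limma, 0.824, moved both ways. It was 0.0699 without the tenth of genes with the smallest SD, 0.140 with array weights and 0.149 without replicate 1. Without replicates 2 and 3 it was 0.99973 and 0.999378. The fit with a replicate block gave 0 genes, 5 Calvin cycle and 11 hydrogenase members over the list alone, against 0, 5 and 8, and changed no call of a gene over all genes. With 3 replicates the simulated test recovered 68.1% of 2-fold changes among genes drawn at random, a share that does not carry over to genes of wide spread. Signal over background was not used here, so what dim spots limit is unknown.

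Members past 0.05 adjusted over the list alone (5 Calvin cycle, 8 hydrogenase) were 0 and 2 on the arabinose-in-Cy3 arrays, 0 and 0 against a 1.2-fold bound, without moderation and with replicate 1 turned, and ranged from 0 to 3 and from 0 to 12 with each replicate left out. Hydrogenase members were 15 on the arabinose-in-Cy5 arrays, 15 with 6 separate arrays and 14 without the genes of smallest spread. Against 8 called lists, 0 were called with an estimated correlation, 0 by fry, 3 by the labels' reading (2 of them among the 8), 6 with replicate 1 turned (1 among the 8) and 8 to 13 with each replicate left out, which held 8, 7 and 6 of the 8 without replicates 1, 2 and 3. By the labels' reading the 2 were the Calvin cycle and ribosomal protein lists, at smaller means of 0.13 and 0.16 (camera adjusted p = 0.0365 and 6.38e-10). The Calvin cycle mean of 0.48 lost its call with an estimated correlation and by fry (0.48, a change of test) and with replicate 1 turned (0.31). Hydrogenase lost its call likewise (0.23, 0.23 and 0.031) and by the labels' reading (0.038). Its mean was 0.42 over the members from blr6922 to bll6944, a limit chosen after the data were seen (0.12 with replicate 1 turned), against 0.23 over the whole list. Genes with a dye effect were 1179 to 1488 with each replicate left out, against 1816. Runs were 3 by sign against 0 by calls. Mean agreement within replicates was 0.489 by Pearson and 0.339 by Spearman.

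Named genes changed sign in 17 of the 300 values that differed from the reported ratio. These were fixI (0.0018) and xylB (0.10) on the arabinose-in-Cy5 arrays, uxuA (0.16) on the arabinose-in-Cy3 arrays, xylB (0.015) with array weights, and with replicate 1 turned pckA (-0.027) and xylB (0.25). With each replicate left out xylB ranged from -0.23 to 0.16 and uxuA from -0.15 to 0.067. By the labels' reading they were bll3466 (0.13), fixI (0.16), nosY (-0.19), nosX (-0.13), sucD (-0.028), pykA (0.0046), uxuB (0.052), xylB (0.13) and rplA (-0.0026).

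List means that changed sign with a replicate left out, as ranges, were nodulation and secretion (-0.084 to 0.015), cbb3 (-0.041 to 0.29), nitrogen assimilation (-0.031 to 0.017), chaperones (-0.21 to 0.48), flagella (-0.14 to 0.048), iron (-0.016 to 0.082), exopolysaccharide (-0.056 to 0.098), sulfur (-0.052 to 0.068) and phosphorus (-0.12 to 0.19). With scaling sulfur was 0.00063. With replicate 1 turned they were NADH dehydrogenase (-0.026), nitrogen assimilation (0.037), pentose catabolism (0.039), exopolysaccharide (-0.087), sulfur (0.095), beta-oxidation (-0.019) and aromatics (0.016). By the labels' reading they were cbb3 (-0.011), oxidases (-0.0014), denitrification (-0.067), pentose catabolism (0.030), flagella (0.015) and beta-oxidation (-0.090).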

Other observations

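The genes named here were chosen after their values were seen. Heat shock genes differed between replicates. The 41 chaperone, heat shock and protease genes had means of -0.64, 0.74 and 0.22 in replicates 1, 2 and 3, and a mean of 0.11 ± 0.70 (camera adjusted p = 0.139). The disaggregase gene clpB (blr1404), 1 of 2 genes with that symbol, had -1.71, 2.55 and 0.62, the chaperonin gene groEL (blr5626), 1 of 5 with that symbol, -1.38, 2.09 and 0.55, and dnaK (blr0678) -1.22, 2.02 and 0.09. The list was called lower without replicate 2 (-0.21, camera adjusted p = 0.00313) and higher without replicate 1 (0.48, camera adjusted p = 6.87e-12) and with replicate 1 turned (0.54 ± 0.28, camera adjusted p = 1.74e-17), where its mean was the highest of the 25 lists. With an estimated correlation these calls had adjusted p = 0.719, 0.688 and 0.699, and by fry 0.866, 0.353 and 0.330. The genes of the cbb3 oxidase subunits fixP (blr2766) and fixQ (bsr2765) had -0.81, 1.36 and 1.00 and -0.94, 1.11 and 0.98. Phosphate and phosphonate uptake had list means of -0.31, 0.31 and 0.07, and flagella and chemotaxis 0.11, -0.26 and -0.01, with means over replicates of 0.02 ± 0.31 and -0.06 ± 0.19 (camera adjusted p = 0.968 and 0.0775). Phosphate and phosphonate uptake was called higher without replicate 1 (0.19, camera adjusted p = 0.0447) and with replicate 1 turned (0.23, camera adjusted p = 0.00600), with adjusted p = 0.688 and 0.699 with an estimated correlation. Flagella and chemotaxis was called lower without replicate 1 (-0.14, camera adjusted p = 0.000877), without replicate 3 (-0.08, camera adjusted p = 0.0191) and with replicate 1 turned (-0.13, camera adjusted p = 0.000571), with adjusted p = 0.737, 0.990 and 0.770 with an estimated correlation.

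The largest SD between replicates of the 8082 genes, with replicate 1 as set from the dyes or turned, was that of blr7593, with -0.64, 3.50 and -3.98 in replicates 1, 2 and 3. The neighbours bll3147, bll3148 and bll3149 had 2.40, 2.49 and 2.24 in replicate 3, 1.26, 1.54 and 0.90 in replicate 2, and -0.36, -0.70 and -0.78 in replicate 1. The ratio of blr7740 was -1.10, 2.73 and 0.17 in replicates 1, 2 and 3, and that of bll3297 was -2.44, 0.42 and 0.36.

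The 17 lists that were not called had camera adjusted p-values from 0.0685 to 0.968, and those not yet described had small means. Terminal oxidases other than cbb3 had 0.09 ± 0.04 (camera adjusted p = 0.0685) and were called without replicate 3 (0.11, camera adjusted p = 0.0417, and adjusted p = 0.861 with an estimated correlation). Carbon monoxide dehydrogenase had -0.08 ± 0.03, storage compounds -0.07 ± 0.0093, nodulation and type III secretion -0.02 ± 0.10, NADH dehydrogenase 0.05 ± 0.11, oxidative stress defence 0.10 ± 0.10, iron and heme 0.02 ± 0.10, beta-oxidation 0.03 ± 0.04 and aromatic degradation -0.02 ± 0.06. The carbon monoxide dehydrogenase list held coxM (bll3785), next to coxN, coxO and coxP of the terminal oxidase list, so it may not hold that enzyme's genes alone. NADH dehydrogenase was called higher without replicate 2 (0.12, camera adjusted p = 0.0265, and adjusted p = 0.647 with an estimated correlation), and nodulation and type III secretion lower without replicate 1 (-0.08, camera adjusted p = 0.0407) and with replicate 1 turned (-0.09, camera adjusted p = 0.00967), with adjusted p = 0.688 and 0.699 with an estimated correlation. The mean of sulfur metabolism was -0.0046 ± 0.13. In 2 lists the mean, median and test differed in sign: nitrogen assimilation had a mean of -0.01 ± 0.05 and a median of 0.0013 with a test pointing up, and exopolysaccharide genes had a mean of 0.01 ± 0.16 and a median of -0.0044 with a test pointing up.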
